A study of Drosophila melanogaster with 2 samples.

How the data were processed

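Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos, 1 day of age, from flies carrying a transgene for the transcription factor Drgx fused to enhanced green fluorescent protein. Per the labels, an antibody against the fluorescent protein was used for the precipitation, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the 2 libraries are biological replicates of 1 group. The labels name a possible control experiment, which was not used here, so no value could be set against a background library.

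The authors deposited 8 peak lists on the dm6 assembly, and the deposited readme texts trace them to the replicates' alignments and 1 further input file. The aligner, the peak caller and their versions are not given in the sources used here. Peaks were scored by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks agree between 2 lists. For each replicate there is a ranked list of all scored peaks and a thresholded list. From both replicates together there are 2 ranked and 2 thresholded lists, and 1 of these thresholded lists is called conservative in its deposited name. The other is called the pooled list here and carries the main results.

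Each peak carries a score of 0 to 1000 set by the authors. In the ranked lists the score differed by at most 1 from the truncated value of 125 times the negative base-2 logarithm of the deposited global IDR, limited to 1000. Each peak also carries a signal value in the deposited lists, whose scale is not given in the sources used here. Signal was larger in lists made from both replicates, so it was used to rank, filter and describe peaks within a list and never as a change between lists. The deposited −log10 q values were read to describe the lists only. Summit positions were taken from the deposited offset of the summit from the peak start. Where the per-replicate ranked lists give it, the signal of the overlapping peak in both lists that the IDR step compared was used for 1 check. The lists hold no read counts, so the depth of the libraries is unknown and no interval that needs it is given.

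Coordinates are 1-based on dm6. Sequence came from the Release 6 reference assembly of NCBI and genes from Ensembl release 115, whose coordinates match dm6, and 0 peaks lay beyond a chromosome end. Analyses used chromosomes X, 2L, 2R, 3L, 3R and 4. Each summit was given the first annotation class that held it, in the order promoter (within 500 bp of an annotated transcription start site, TSS, of any gene), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Transposable elements were left out of the gene set.

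Overlap between replicates required at least 1 bp and was compared with 1000 circular rotations of 1 list along each chromosome, with a one-sided p. Annotation classes were compared with 1000 rotations of the summits, two-sided. Chromosome shares were compared with chromosome length by an exact binomial test, which covers counting error only because peaks cluster. The 20 preset words, written on both strands, were counted in the 101 bp window centred on each summit and in a window of the same size 500 bp to its left, and compared by the exact McNemar test, two-sided. The same test was run for all 2080 6-base words, counting a word and its reverse complement as 1. Gene lists were compared by Fisher's exact test, two-sided, on whether a gene has a summit within 1000 bp of a TSS, against all other protein-coding genes, of which the 6 chromosomes hold 13945. Of the gene symbols listed, 4 were not matched unambiguously to a gene in the annotation and were left out. They were crys (epidermis and cuticle list), lines (endoderm and gut), nos (germline) and Dl (signalling ligands and receptors). Correlations are across peaks, which are not independent replicates, with permutation p from 100000 resamples, or from 1000 for the ranked lists. Adjusted p-values are Benjamini-Hochberg values within each family, and 0.05 was the threshold. The smallest p that the rotations can give is 0.001 one-sided and 0.002 two-sided, and the smallest from 100000 permutations is 1e-05.

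Lists, words, the main tests, the settings varied and the rule for naming genes were fixed before the data were examined. Tests of the preset words split by annotation class or by signal were not in that plan. Nor was the overlap of peaks without a thresholded partner with the other replicate's ranked list. The rule names Drgx, then the 20 peaks of highest signal in the pooled list that overlap a thresholded peak of both replicates, each by the protein-coding gene with the nearest TSS. It also names up to 4 members of each gene list past the threshold and up to 2 of each other list, by the highest signal of a summit within 1000 bp of a TSS. Of the 6-base words it names the 5 with the largest excess and the 3 with the largest deficit. Alternatives were the conservative list, each replicate's own list, the stronger peaks, other overlap rules, promoter widths, windows, controls and nulls, and 10000 random gene lists matched on gene length, number of TSSs and distance to neighbouring genes. A setting that drops each weaker peak within 500 bp of a stronger one was added after seeing the data.

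The overlap, location, word and gene list tests were tested on simulated data. In 6000 simulated peaks with 50% shared, 51.5% were found to overlap. With 40% of 6000 random summits placed in promoters, the promoter share was 48.0%, and a fully random list gave 0 classes past the threshold. A word written into 10% of 6000 random windows gave a difference of 9.18 percentage points and ranked first among the 6-base words, and with no word planted 0 words passed. Among the 13945 genes, 0 lists passed with none planted and 1 passed with 1 planted. The simulated summits were placed, and the simulated genes marked, independently at random. Real summits are AT-rich and clustered, so these simulations do not show the rate of false calls in the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.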

Results

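Drgx is a transcription factor of the paired-like homeodomain class, a family whose members bind AT-rich sites with the core TAAT. The series recorded ChIP-seq peaks obtained with an antibody against the tag in 1-day whole embryos, in 2 biological replicates of 1 group. Which peaks come from the tagged protein itself was not tested. With 1 group and no control library used here, the comparisons open to the design are between the replicates and between the peaks and the genome. The pooled list held 8443 peaks covering 2.79 Mb, which is 2.03% of the assembled chromosomes, and the conservative list held 7909. Replicate 1 on its own gave 6349 peaks and replicate 2 gave 5475, a ratio of 1.16. Width carried little information, as 74.6% of peaks in the pooled list had the same width of 384 bp. All peaks of the 4 thresholded lists had a score of at least 830, which corresponds to an IDR of 0.01. The depth of the libraries is unknown, since the files hold peaks and no read counts.

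The replicates shared most of their peaks. Of the replicate 1 peaks, 4373 (68.9%) overlapped a replicate 2 peak, where rotated lists gave 2.42% ± 0.227 (SD over 1000 rotations). In the other direction 4271 of the replicate 2 peaks (78.0%) overlapped, against 2.77% ± 0.257. Both had a permutation p = 0.001 from the rotations, the smallest these can give. Sharing followed signal: 98.2% of the 1588 strongest replicate 1 peaks had a partner and 36.5% of the 1587 weakest. Of the 1976 replicate 1 peaks with no thresholded partner, 94.9% overlapped a peak of the replicate 2 ranked list, against 32.7% ± 1.71 (SD) after rotation (permutation p = 0.001, the smallest possible). Across the 4373 overlapping peaks, signal in both replicates was correlated, with Pearson's r = 0.666 on log2 signal and Spearman's rho = 0.744, each with a permutation p of 1e-05, the smallest possible. Among the 59452 overlapping peaks of the ranked lists, rho was 0.481 (p = 0.001, the smallest possible there). For the 4007 thresholded replicate 1 peaks with a replicate 2 summit within 100 bp, r was 0.843 and rho 0.807 (permutation p = 1e-05 each).

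The strongest peak lay in an intron of CG11050, 1022 bp downstream of the TSS, at 2L:6612384-6612995, with a signal of 3414 in the pooled list, 2071 in replicate 1 and 1308 in replicate 2. It was followed by the promoter of Ugalt, a UDP-galactose transporter gene (X:2703693-2704067, 3192 pooled, 1772 and 1435 in the replicates), and that of CG14100 (3L:19590454-19590777, 2235). Of the 20 strongest peaks found in both replicates, 13 were at promoters, 4 in introns, 2 between genes and 1 in another exon. The other promoter peaks included those of PNPase, a mitochondrial RNA-degrading enzyme gene (2226), CG18549 (2152), CenG1A (1920), CG7601 (1918), the Polycomb group gene ph-p (1840), Tcs5 (1837), the small heat shock protein gene Hsp27 (1827), Fkbp14 (1769) and the mitochondrial ribosomal protein gene mRpL41 (1731). At eEF1gamma (1722) and CG4004 (1653) the summit lay more than 5000 bp from the TSS of these nearest coding genes, at the promoter of a non-coding RNA gene. Intron peaks were at CG32772 (1895), near CG16753 (1880) and in Trl, which encodes the GAGA factor (1726). The peak in osa, a subunit gene of the Brahma chromatin remodelling complex, lay in an exon 13924 bp downstream of the nearest TSS (1778). Peaks between genes were nearest to CG31668 (2157) and CG13323 (2152). TAATTA was present within 50 bp of 5 of these 20 summits and the spaced dimer TAATNNNATTA at 0.

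At the Drgx gene itself (FBgn0085369, 2L:3662745-3692114, plus strand), the pooled list held 3 peaks within the gene and 10 kb on either side. The strongest, at 2L:3655648-3655981, ranked 22 of 8443 with a signal of 1587, and it ranked 23 in replicate 1 and 26 in replicate 2. Its summit lay 6924 bp before the Drgx start, in an intron of foraging (for), a cGMP-dependent protein kinase gene on the minus strand, which is named here because of its position. A second peak at 2L:3657622-3658005, between for and Drgx, had a signal of 236 and was present in both replicates. The pooled peak inside Drgx, in an intron at 2L:3688148-3688531, had a signal of 64.2 and no thresholded partner in either replicate. Replicate 1 alone had another thresholded peak inside Drgx, in an intron at 2L:3667159-3667538 (signal 52.4, rank 5719), which the pooled list lacks. Across the locus the pooled list had 60.8 peaks per Mb, against 63.1 for the whole list. The thresholded lists of replicates 1 and 2 had 60.8 each, against 47.4 and 40.9. The conservative thresholded list had 2 peaks there, 40.5 per Mb against 59.1. No test was made for 1 locus. The peaks behind these values were not the same sites in each list. Replicate 2 had overlapping peaks between for and Drgx, at 2L:3657591-3657894 (signal 81.6) and 2L:3657794-3658097 (15.3). The 4 ranked lists were sparser there, with 101.3 against 726.8 (pooled), 243 against 721 (conservative), 324 against 642 (replicate 1) and 344 against 582 (replicate 2). The flies carry a Drgx transgene, and reads from any sequence it shares with this locus would be placed here too. The lists cannot tell such reads from those of the gene's own copy, for signal, rank or density.

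Peak summits concentrated at promoters. Promoters held 3105 of 8443 summits (36.8%), 2.72 times the 13.5% ± 0.587 (SD) of rotated summits, and introns held 45.0% against 39.4% ± 0.960. Coding exons held 1.22% against 13.6%, 3' UTRs 0.805% against 4.43%, and intergenic sequence 14.6% against 27.4%. These 5 classes each had an adjusted p of 0.0028, the smallest the rotations can give. The shares in 5' UTRs (0.746% against 0.784%, rotation permutation adjusted p = 0.739) and other exons (0.865% against 0.810%, adjusted p = 0.739) did not differ from rotation. With promoters widened to 1000 bp, the intron excess was no longer past the threshold (1.05 times, permutation adjusted p = 0.0886), and 5' UTRs fell below rotation (0.472 times, adjusted p = 0.0028).

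**Figure D1:**
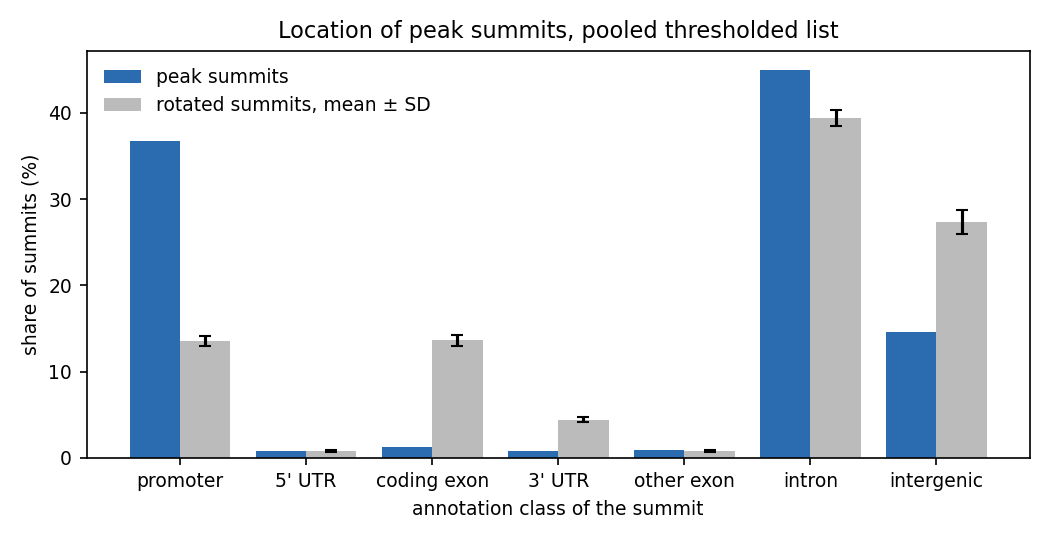
Share of the 8443 summits of the pooled list in each annotation class (%, blue bars) beside the mean of 1000 rotations (grey bars, error bars SD). Promoters hold 36.8% of summits against 13.5% after rotation, and coding exons 1.22% against 13.6%.

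Chromosome 4, the small chromosome also called the dot, was nearly free of peaks. It held 2 of 8443 (1.48 per Mb), which is 0.0235 times its share of the length (exact binomial adjusted p = 3.16e-33). They were a promoter peak of the axon guidance receptor gene PlexA (4:1027229-1027378, signal 186, 88.8 and 89.4 in the replicates) and a peak downstream of Sox102F (4:799369-799752, signal 72.5), named after its value was seen, with no thresholded partner in either replicate. X had the highest density, 70.8 peaks per Mb and 1.12 times its share (exact binomial adjusted p = 9.93e-07), and 3L had 1.08 times (adjusted p = 0.000295). The share was 0.933 times the length on 3R (exact binomial adjusted p = 0.000825) and 0.949 times on 2R (adjusted p = 0.0302), and 2L did not differ (0.983, adjusted p = 0.466). The 2R difference was not past the threshold in the conservative list (0.962, exact binomial adjusted p = 0.125) or in the replicate 1 list (0.960, adjusted p = 0.124). These p-values cover counting error only, and peaks cluster, with a variance 4.06 times the mean in bins of 50 kb. The evidence for the small departures of X, 3L, 3R and 2R is therefore overstated.

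Summit windows were AT-rich, with 36.9% G and C against 41.7% in the windows 500 bp to the left. The homeodomain core TAATTA occurred at 673 summits (7.97%) and in 552 control windows (6.54%), a difference of 1.43 percentage points (McNemar's exact test, adjusted p = 0.00235). The paired-class dimer TAATNNNATTA was at 1.39% against 0.758% (exact adjusted p = 0.000912) and TAATNNATTA at 1.07% against 0.651% (adjusted p = 0.0131). Each call was lost in the list of 1 replicate, TAATTA (0.895 points, exact adjusted p = 0.128) and TAATNNATTA (0.420 points against 0.415 in the pooled list, adjusted p = 0.0848) in replicate 2 and TAATNNNATTA (0.410 points against 0.628, adjusted p = 0.0737) in replicate 1, and TAATTA also with 100 bp either side (0.533 points, adjusted p = 0.388). Against random windows of the same chromosome and the same G and C content, the TAATTA difference turned negative (7.97% against 9.08%, exact adjusted p = 0.0346). The dimers were then no longer past the threshold (differences of 0.237 points for TAATNNNATTA, exact adjusted p = 0.469, and 0.0592 points for TAATNNATTA, adjusted p = 0.931).

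Among the words of other factors, GAGAGAG, the site of the GAGA factor, was higher at summits (2.93% against 2.07%, exact adjusted p = 0.00235), as was GGTCACAC, a core promoter word bound by M1BP (0.497% against 0.190%, adjusted p = 0.00345). GGTCACAC was 2.63 times as frequent at summits and did not pass in replicate 2 (2.30 times, exact adjusted p = 0.0877), in replicate 1 (2.17 times, adjusted p = 0.0737), among the 4221 strongest peaks (2.33 times, adjusted p = 0.231) or against the window to the right (1.35 times, adjusted p = 0.322). GAGAGAG, 1.41 times as frequent, did not pass in the replicate 1 list (1.22 times, exact adjusted p = 0.191). GAGAGAG was raised at promoter summits, 4.32% against 2.09% (exact adjusted p = 2.78e-05), and not in introns and intergenic sequence, 1.97% against 2.03% (adjusted p = 1); the difference between these parts was not tested. Over the 1689 strongest peaks it was instead lower at summits, 1.01% against 3.02% (exact adjusted p = 0.000891). Words lower at summits were the E boxes CACCTG (2.19% against 3.85%, exact adjusted p = 7.88e-09) and CAGCTG (3.34% against 4.11%, adjusted p = 0.0227, lost with 100 bp either side at 0.223), and AACCGG, a Grainy head site (1.55% against 2.25%, adjusted p = 0.00364). The other 12 words, namely TAATCC, TTTATG, TGACAG, GATAAG, CATATG, CAGGTAG, TATCGATA, TGAGTCA, CATTCCA, ATTTGCAT, ACAATAG and CCGGAAG, did not pass the threshold in the pooled list against the neighbouring window. Among the 4221 strongest peaks TTTATG was higher (12.9% against 10.8%, exact adjusted p = 0.00818), and it was higher in replicate 1 (adjusted p = 0.0384) and lower than in windows of matched G and C content (adjusted p = 0.0319). Under at least 1 alternative TAATCC, TGACAG, CAGGTAG and ATTTGCAT passed as lower, and TATCGATA and ACAATAG as higher. With matched G and C content GAGAGAG remained higher (0.900% in matched windows, exact adjusted p = 1.56e-21) and so did GGTCACAC (0.154%, adjusted p = 0.00114), and CATATG was higher too (3.59% against 2.84%, adjusted p = 0.0346), while CAGCTG and AACCGG turned to small positive differences that did not pass and CACCTG no longer passed (adjusted p = 0.0761).

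**Figure D2:**
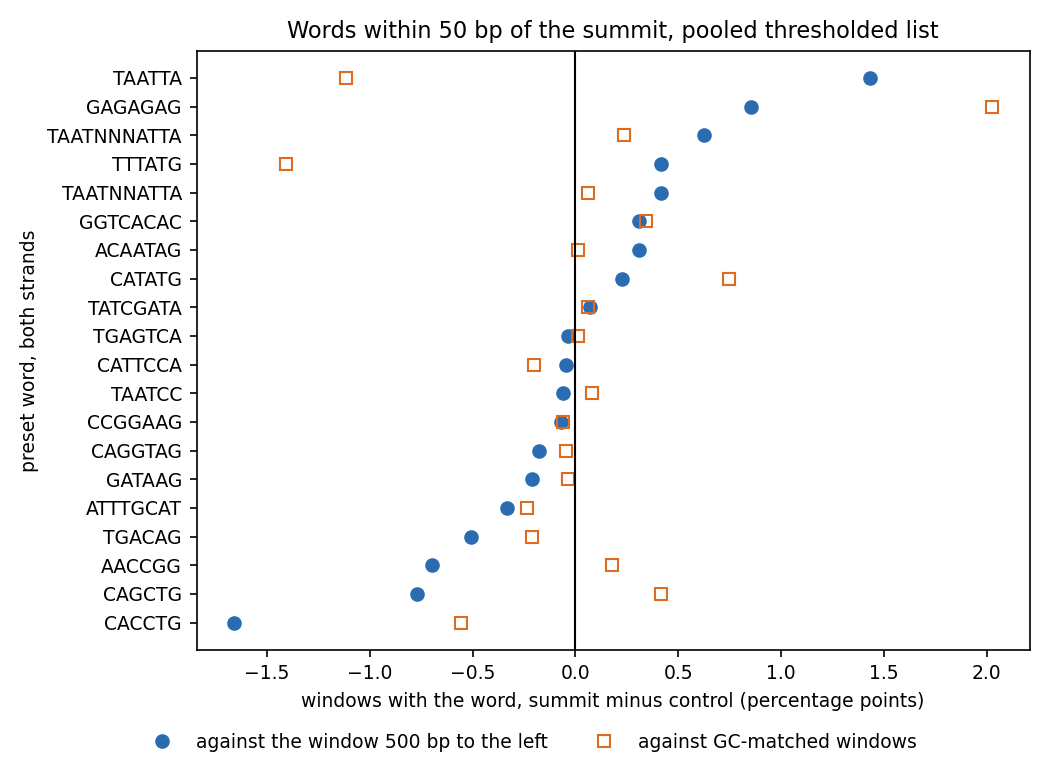
Difference in the share of windows holding each of the 20 preset words, summit minus control, in percentage points, against the window 500 bp to the left (filled circles) and against windows of matched G and C content (open squares), over 8443 summits. TAATTA lies at 1.43 points against the neighbouring window and at -1.11 points against matched windows.

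Over all 2080 6-base words, 351 were more frequent at summits and 774 less frequent. The 5 with the largest excess were runs of A and T: AAAATA (32.3% against 21.5%, exact adjusted p = 3.65e-53), AAAAAT (32.2% against 23.1%), AAAAAA (29.4% against 20.3%), AAATAT (26.7% against 17.6%) and TTAAAA (25.3% against 16.4%). The 3 with the largest deficit were GGCCAA (4.63% against 8.01%, exact adjusted p = 7.68e-18), TGGCCA (2.83% against 5.82%) and GCCAAA (8.15% against 11.0%). TAATTA ranked 208 by excess. With matched G and C content, 216 words were higher and 271 lower, of which 67 and 204 were also called in the main comparison, and TAATTA ranked 1986.

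TAATTA was more frequent at stronger peaks. It was present at 10.5% of the 1689 strongest summits and 6.10% of the 1688 weakest, and across all 8443 peaks rho between signal and its presence was 0.0525 (permutation p = 1e-05, the smallest possible). Windows of matched G and C content rose likewise, to 12.3% for the 1689 strongest from 5.86% for the weakest. The relation was small, and among the 4221 strongest peaks it did not pass (rho = 0.0243, p = 0.115).

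Of the 13945 protein-coding genes, 3516 (25.2%) had a summit within 1000 bp of a TSS. Of 23 gene lists, 2 were above the other genes and 1 below. The cytoplasmic ribosomal protein genes had a summit at 45 of 92 (48.9%, exact 95% interval 38.3 to 59.6%) against 25.1% of other genes, a log2 odds ratio of 1.52 (Fisher's exact adjusted p = 1.57e-05). Their strongest members were RpS19b (signal 800), whose strongest summit lay 902 bp from the TSS in an intron of CG5854, RpL34b (357), RpL32 (314) and RpS20 (279), the last 3 at promoters. With the 4221 strongest peaks alone the list had 16 of 92 (17.4%, log2 odds ratio 0.29, Fisher's exact adjusted p = 0.792) and did not pass.

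Signalling ligands and receptors had a summit at 22 of 49 genes (44.9%, interval 30.7 to 59.8%) against 25.1%, a log2 odds ratio of 1.28 (Fisher's exact adjusted p = 0.0204). They were led by sty, which encodes the receptor tyrosine kinase inhibitor Sprouty (1056 pooled, 645 and 416 in the replicates), spi, a ligand of the EGF receptor (500), wit, a BMP receptor gene (365) and aos, an EGF receptor antagonist gene (240). This call was lost in the replicate 2 list (15 of 49, log2 odds ratio 1.03, Fisher's exact adjusted p = 0.219), with the 4221 strongest peaks, at a log2 odds ratio of 1.36 (adjusted p = 0.0515), and against lists matched on gene length, TSS number and spacing (36.0%, permutation adjusted p = 0.556). Odorant, gustatory and ionotropic receptor genes, which mark mature chemosensory neurons, had a summit at 5 of 179 (2.79%, interval 0.913 to 6.40%) against 25.5%, a log2 odds ratio of -3.44 (Fisher's exact adjusted p = 4.92e-15). The highest signals among these few were those of Or88a (146), Ir60e (137), Ir60b (107) and Ir67c (98.4), the last 2 with no thresholded partner in replicate 2. With summits up to 5000 bp from a TSS the list had 49 of 179 (27.4% against 49.1%, log2 odds ratio -1.35, Fisher's exact adjusted p = 9.93e-08), and with summits within 500 bp the log2 odds ratio was -4.25.

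**Figure D3:**
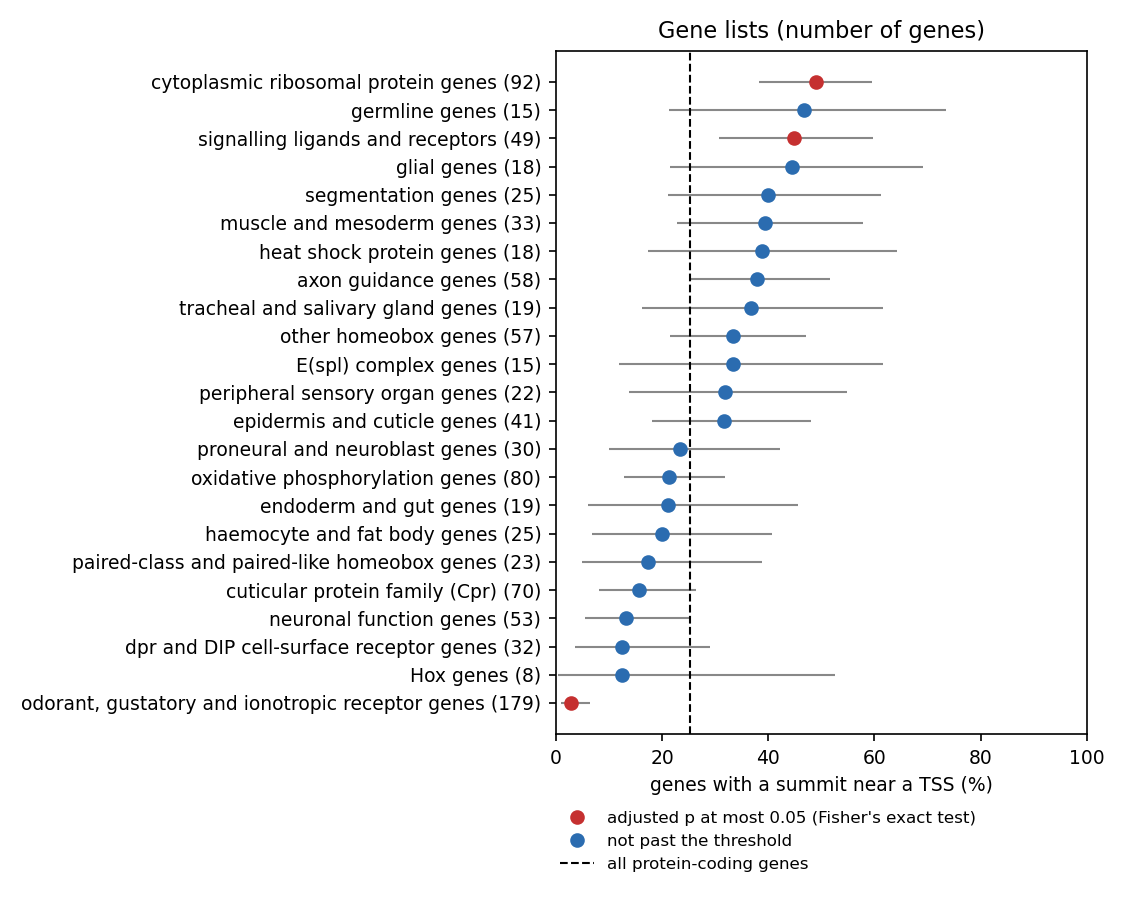
Share of genes in each of the 23 lists with a summit within 1000 bp of a TSS (%, points; bars are exact 95% intervals; number of genes in brackets), with all protein-coding genes as the dashed line at 25.2%. Ribosomal protein genes (48.9%) and signalling genes (44.9%) lie above it and chemosensory receptor genes (2.79%) below it, in red.

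None of the neural lists passed in the main comparison. Axon guidance genes had a summit at 22 of 58 (37.9%, Fisher's exact adjusted p = 0.189), among them unc-5 (269) and PlexA (186). Glial genes had 8 of 18 (44.4%, Fisher's exact adjusted p = 0.222), with moody (868) and loco (323), peripheral sensory organ genes 7 of 22 (31.8%, adjusted p = 0.647), with Piezo (357, no thresholded partner in replicate 1) and ct (244), and proneural and neuroblast genes 7 of 30 (23.3%, adjusted p = 1), with brat (775) and hb (488). Neuronal function genes had 7 of 53 (13.2%, Fisher's exact adjusted p = 0.209), with elav (928, 582 and 338 in the replicates) and Sh (266). Genes of like length, TSS number and spacing had 41.3%, and against these the neuronal list was lower (permutation adjusted p = 0.00153). The dpr and DIP receptor genes had 4 of 32 (12.5%, Fisher's exact adjusted p = 0.222), with dpr20 (402) and dpr14 (351), and were lower when summits up to 5000 bp from a TSS were counted (log2 odds ratio -2.60, adjusted p = 0.000251).

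Homeobox lists did not pass either. Paired-class and paired-like genes, the class of Drgx, had a summit at 4 of 23 (17.4%, Fisher's exact adjusted p = 0.647), among them oc (132) and Ptx1 (85.1, no thresholded partner in replicate 2). Hox genes had 1 of 8 (12.5%, Fisher's exact adjusted p = 0.754), which was Antp (73.4) with no thresholded partner in either replicate. Other homeobox genes had 19 of 57 (33.3%, Fisher's exact adjusted p = 0.321), led by NK7.1 (818) and Dll (784), the latter at the promoter with 533 in replicate 1 and 244 in replicate 2.

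The remaining 11 lists did not pass. Segmentation genes had 10 of 25 (40%, Fisher's exact adjusted p = 0.222), including hb and nkd (407). Muscle and mesoderm genes had 13 of 33 (39.4%, Fisher's exact adjusted p = 0.209), with tin (527) and Msp300 (516), and germline genes 7 of 15 (46.7%, adjusted p = 0.209), with Btk (1434) and orb (382). Heat shock protein genes had 7 of 18 (38.9%, Fisher's exact adjusted p = 0.321), led by Hsp27 and Hsp26 (553), and tracheal and salivary gland genes 7 of 19 (36.8%, adjusted p = 0.473), with fkh (176) and bnl (174). E(spl) complex genes had 5 of 15 (33.3%, Fisher's exact adjusted p = 0.667), with E(spl)mdelta-HLH (258) and E(spl)mbeta-HLH (137), and epidermis and cuticle genes 13 of 41 (31.7%, adjusted p = 0.563), with Cht7 (409) and Cpr64Aa (192). Oxidative phosphorylation genes had 17 of 80 (21.3%, Fisher's exact adjusted p = 0.662), with ND-ASHI (711) and ND-MWFE (244), and endoderm and gut genes 4 of 19 (21.1%, adjusted p = 0.833), with bowl (953) and fkh. Haemocyte and fat body genes had 5 of 25 (20%, Fisher's exact adjusted p = 0.748), with Adh (210, no thresholded partner in replicate 2) and crq (128), and cuticular protein genes of the Cpr family 11 of 70 (15.7%, adjusted p = 0.209), with Cpr62Ba (249) and Cpr64Aa. The Cpr family was lower in the replicate 2 list (log2 odds ratio -1.71, Fisher's exact adjusted p = 0.0349) and when only summits within 500 bp of a TSS were counted (-2.86, adjusted p = 0.000172), and the muscle list was higher at 5000 bp (1.44, adjusted p = 0.0306).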

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

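The tests on scaling at chromosome 4 and on weak peaks beside strong ones were chosen only after the result was seen, as were the reading of the sign of the flank correlation and the test of TAATTA over the 3378 strongest summits. The design has 1 group, so no biological explanation was tested between groups, while homeodomain cores, promoter sequence and separate weaker sites were tested within the peaks.

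Ranked peaks appeared on sequences that the comparisons leave out. The pooled ranked list held 51 peaks on the Y chromosome and 608 on sequences outside X, Y and the autosomes, although 0 of the thresholded peaks lay there. The highest signal among these was 25.7 on Y and 84.4 elsewhere, against a median of 120 in the pooled thresholded list. Of these peaks, 2 outside Y had a score of at least 830, the lowest in the thresholded list, as did 185 pooled ranked peaks in all that the thresholded list lacks, for a reason not given in the sources used here.

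Chromosome 4 held 2 thresholded peaks where its length would give about 1.01% of 8443. Repeated sequence as the cause is argued against, since 83.1% of its 31-base words occur once in the assembly, close to the 83.2% of 2R. A mask over most of the chromosome stays open. Of its 27 bins of 50 kb, 12 (44.4%) held a ranked peak of at least 1 list, which met the bound set beforehand against a mask. A bin counts with 1 peak, however, so a mask with gaps could leave peaks in as many bins. Low read coverage or scaling against a control stays open and goes with the values: weak peaks were missing too, the pooled ranked list having 0.0236 times the density of the main arms there, and the replicates 0.0302 and 0.0599 times. A property of this chromosome's chromatin may equally give few peaks and is untested.

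Summits of strong peaks were AT-rich, from 30.4% ± 7.72 (SD) G and C within 50 bp at the 845 strongest to 44.5% ± 10.4 at the 844 weakest (rho = -0.383 across all peaks, 95% bootstrap interval -0.401 to -0.365; -0.344 in replicate 1 and -0.343 in replicate 2). A composition bias at the scale of sequenced fragments would make the flanks of strong peaks AT-rich too. Beyond 100 bp and up to 400 bp from the summit, rho was instead 0.138 (interval 0.117 to 0.159), of the opposite sign. Its size was 0.361 times that at the summit and so not under the bound of 0.25 set beforehand. At 51 to 100 bp the strongest peaks remained lower in G and C, 39.9% against 43.9% in the weakest. Promoters held 48.6% of the strongest and 34.0% of the weakest, and the flank values were not split by class. A composition bias over a shorter range therefore stays open. Promoter sequence as the whole cause is argued against by a rho of -0.335 among the 5031 summits in introns and intergenic sequence. The core TAATTA is argued against as well, being 1.78 percentage points rarer at the 1689 strongest summits than in windows of matched G and C content (a difference of -1.78, McNemar's exact p = 0.114) and 2.25 points rarer over the 3378 strongest (-2.25, p = 0.00214). Other AT-rich sites stay open, as 216 6-base words were more frequent over all summits than in matched windows, AAAAAA with the largest excess, and open chromatin in general and a background of the antibody were not tested.

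Weak thresholded peaks of the pooled list stood beside strong ones: of the 305 pooled peaks with a signal under 30, 290 (95.1%) had a peak of at least 60 within 500 bp, at a median distance of 204 bp. Separate weaker sites would lie at varied distances if every distance could be reported, whereas 95.5% of these distances were 150 to 250 bp. Most pooled peaks had the same width of 384 bp, and the peak caller, which is not given, may limit the distances between summits. The distances therefore do not exclude separate sites. With the same cut-offs of 30 and 60, such neighbours stood at 224 of 304 weak peaks in replicate 1 and 60 of 194 in replicate 2. Median signal was 87.2 and 70.4 in these lists and 120 in the pooled list. The cut-offs are thus not equally strict, and the shares cannot be compared between lists. Pairing of a weak shoulder with its strong neighbour in the compared lists stays open: the paired signal was a median 5.69 times the weak peak's own over both replicates, but 3.57 times in replicate 2, under the bound of 4 set for it, against 6.25 in replicate 1. Weak peaks with no strong neighbour had 2.55 times in replicate 1 and 2.88 in replicate 2. Strong peaks had 0.501 times in replicate 1 and 0.4997 in replicate 2. Weak peaks counted as having no strong neighbour may still stand beside a peak of 30 to 60. Whether the choice of weak peaks by itself raises the ratio was therefore not tested.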

How the results depend on the processing

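Of 478 alternative values, 422 stayed past the threshold in the same direction, stayed short of it, or, for counts, stayed within 1.5 times. The peak counts did so with overlapping peaks merged, and an IDR of 0.01 tested nothing, being the threshold the lists already meet. The setting without weaker peaks within 500 bp of a stronger one, chosen after seeing the data, ended no call. Promoter, intergenic and chromosome 4 results and the replicate overlap kept their calls under every alternative run.

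With windows of matched G and C content the TAATTA difference was -1.11 percentage points, that of TAATNNNATTA 0.237, of TTTATG -1.41, of CAGCTG 0.415 and of AACCGG 0.178, and 216 6-base words were higher and 271 lower against 351 and 774. These windows differ from the neighbouring ones in composition and in place. The TAATTA difference was 0.533 with 100 bp either side. GAGAGAG turned to -0.379 among the 4221 strongest peaks, where rho of TAATTA with signal was 0.0243. In the lists without 1 replicate, TAATTA ranged from 0.895 to 1.89 and TAATNNNATTA from 0.410 to 0.621. The number of gene lists above the others was 2, and 1 to 2 without 1 replicate, 0 with the 4221 strongest peaks, 3 at 5000 bp and 1 against matched lists. The number below was 1, and 1 to 2 without 1 replicate, 2 at 500 bp, 3 at 5000 bp and 2 against matched lists. For all of these the cause was not tested. Besides TAATTA and TAATNNNATTA, 16 values of single words, classes, chromosomes and lists lost their call with the direction kept, 21 gained one, and the 4 of TTTATG, CAGCTG, AACCGG and GAGAGAG turned.

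No paired analysis was possible because there is 1 group. Depth is unknown, so a weak or absent peak cannot be told from a shallow library.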

Other observations

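All values here were chosen after the data were seen, and they carry no explanation.

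Promoter summits sat just upstream of the TSS. Of 2852 summits within 500 bp of a protein-coding TSS, 1963 (68.8%, exact 95% interval 67.1 to 70.5%) were upstream, at a median distance of 142 bp, and 33.5% of all of them lay 100 to 250 bp upstream. By kind of gene, a summit lay within 500 bp of a TSS at 20.9% of 13945 protein-coding genes, 3.01 times the mean of 200 rotations (permutation adjusted p = 0.035, from p = 0.01, the smallest these rotations can give), at 10% of 3261 non-coding RNA genes (1.68 times, adjusted p = 0.035) and at 35 of 290 tRNA genes (12.1%, 2.08 times, adjusted p = 0.0464). Pseudogenes had 8 of 268 (2.99%, 0.507 times, permutation adjusted p = 0.209), snoRNA genes 22 of 269 (8.18%, adjusted p = 0.453) and snRNA genes 4 of 32 (12.5%, adjusted p = 0.334). For rRNA genes it was 0 of 99, against 6.66% ± 8.36 (SD) after rotation (permutation adjusted p = 0.647).

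Peaks were unevenly spread. In bins of 50 kb the mean was 3.15 peaks and the variance 4.06 times the mean, and 915 of 2680 bins (34.1%) were empty where a Poisson spread gives 4.28%. The fullest bin, with 26 peaks, was 3L:750001-800000 and holds emc, which encodes the helix-loop-helix inhibitor Extramacrochaetae, and hng3. Another crowded bin, 2R:18300001-18350000, held 23 around sbb, CG14505, CG18540 and Tango8. At the other end, 36 stretches of at least 200 kb between neighbouring summits were empty. A stretch of 310 kb at 2L:21314127-21623819 held the histone genes, and 1 of 832 kb at X:21630015-22461540 was the longest. Whether sequence can be placed uniquely was examined per chromosome only. Empty bins and stretches may therefore hold sequence where reads cannot be placed, and need not be free of binding.

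A word outside the homeodomain class, CACAGTG, was at 2.37% of all 8443 summits, 1.28% of control windows (McNemar's exact adjusted p = 1.44e-06) and 0.900% of matched windows (adjusted p = 1.42e-12). It was present at 3.55% of 1689 summits of the fourth signal class of 5, ordered from the strongest, against 0.710% in control windows (McNemar's exact adjusted p = 1.61e-07) and 1.36% in windows of matched G and C content (adjusted p = 0.000358). Over the 1689 strongest summits it was at 1.66% against 1.48% in control windows (exact adjusted p = 0.809) and 0.710% in matched windows (adjusted p = 0.0332). The related word GCACTGA was at 2.16% of all 8443 summits, 1.08% of control windows (exact adjusted p = 5.48e-07) and 1.05% of matched windows (adjusted p = 1.77e-07), and at 0.947% of the 1689 strongest summits against 1.18% in control windows and 0.888% in matched windows. Neither word was among those fixed in advance. Both were picked after the data were seen and were tested on the same summits. Their adjusted p-values do not cover the search that found them, so the evidence is overstated. The fourth signal class was likewise picked, as the one of 5 with the largest excess of CACAGTG.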
